A study of Mus musculus with 3 samples.

How the data were processed

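Gene expression was measured in CLDE cells, a mouse dental epithelial line derived from the cervical loop, the stem cell niche at the growing end of the incisor. Cells were harvested 72 h after transfection. The 3 arrays were a mock transfection, a non-targeting siRNA (siNeg) and an siRNA against keratin 15 (siKrt15), with 1 array per group. For 2 of the arrays the labels contradict each other: the title and source name give siNeg or siKrt15, and the description and treatment field give the other. Groups were taken from the titles before the data were examined, so "the siKrt15 array" means the array titled so throughout.

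Cy3-labelled cRNA from total RNA was hybridised to 1-colour Agilent mouse arrays, per the labels' protocols. The submitters' processing notes name Agilent Feature Extraction 11.5.1.1, and per the file headers the extraction protocol was GE1_1105_Oct12 and probe coordinates are on mm9. The deposited scanner files give, per spot, a background-subtracted processed signal as an intensity on a linear scale in arbitrary units. The series value table holds values that the authors deposited on a log2 scale. Set against the scanner files, it follows the log2 processed signal minus a constant close to each array's 75th percentile, with no centring of genes. After that constant 93.8% (mock), 94.0% (siNeg) and 92.4% (siKrt15) of probes lay within 0.01. Its medians are −3.52 for mock, −3.51 for siNeg and −3.72 for siKrt15. The scale and direction of that table were settled by this comparison, with a Pearson r across probes of 1.00 for each array.

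Each array held 62976 spots, of which 59305 were not controls, and 56598 probes had values on all 3 arrays. Spots well above background numbered 40901 (69.0%) for mock, 41025 (69.2%) for siNeg and 39883 (67.3%) for siKrt15. No spot was saturated (0 on each array). Outlier spots were left out, 69 on mock, 68 on siNeg and 85 on siKrt15. The 75th percentile of the processed signal was 191.1 for mock, 180.4 for siNeg and 216.0 for siKrt15. Among the 300 probes spotted 10 times, the median SD of replicate spots was 0.05 on the log2 scale on each array. The scanner's error model gave a median SD of 0.21 for a gene's log2 difference between arrays, with a 95th percentile of 0.35. For most bright genes the model gave nearly the same SD, 0.204 for Rpl4, Rpl10 and Rps14 alike. It is therefore not a spread measured for each gene. Both errors concern 1 hybridisation per group, and the number of arrays limits the precision.

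Normalized signal was the log2 processed signal minus each array's 75th percentile, with spots of a probe averaged on the log2 scale. Probes were named through the RefSeq table of GRCm38.p6, used for names only: 32989 probes matched by accession, 10224 by symbol and 520 by synonym, giving 24812 genes, and 12865 probes kept the name in the files. A probe was measured in a comparison if it was well above background and not saturated on both arrays. A gene's difference was the mean over its measured probes, and a gene was counted at a difference of at least 2-fold. Where a gene was well above background on 1 array only, the brighter value was set against the higher of the dim probe's own value and the lowest value well above background on that array, and given as "at least N-fold".

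With 1 array per group there was no test across arrays, and no p-value was computed. For 23 gene lists fixed at the same stage as the groups, the list median was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, and its position relative to their central 95% was recorded. This describes these arrays only. If genes varied independently, 1.15 of 23 lists would lie outside by chance. Genes of a list can vary together, and siNeg against mock alone put 6 of 23 lists outside. Named genes were chosen by a rule written beforehand: Krt15, the 10 highest and 10 lowest genes in siKrt15 against both controls, the 5 highest and 5 lowest of siNeg against mock, the 3 brightest genes above background only in siKrt15 and the 3 brightest in both controls only, up to 4 members per list with the largest siKrt15 to siNeg difference, and the keratins. The ranked genes had a proper symbol and a mean signal at or above the 25th percentile. Their probes measured on all 3 arrays all went the same way. Some list members that this rule names are not reported here.

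The procedure was tested on simulated arrays over 16912 genes. They were made from the mean of the siNeg and mock arrays, with errors drawn from the differences between those 2 controls. The wider spread of siKrt15 against siNeg (SD over all genes 0.42, against 0.23 for siNeg and mock) did not enter. Of 50 genes changed 1.5-fold, 4 (8%) passed the 2-fold threshold, against 45 (90%) at 2.5-fold, 48 (96%) at 3-fold and 50 (100%) at 4-fold. Of 16712 unchanged genes, 50 (0.299%) passed, and 14 of 300 random null lists (4.67%) fell outside the central 95%. The null lists held random genes with independent errors, so that rate does not cover lists of genes that vary together.

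The alternatives chosen at that stage were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), quantile normalization, scaling to the median of probes above background, the deposited log2 table, no filter or a stricter filter on dim probes, the brightest probe per gene, groups taken from the descriptions, and thresholds of 1.5-fold and 3-fold. Added after seeing the data were scaling to the 9 spike-in probes, removal of the signal-dependent trend, the 75th percentile over spots and 4 gene lists. The spike-ins differed by 0.02 between siKrt15 and siNeg, where the 75th percentiles differed by 0.26. Spike-in scaling therefore moved the median of all genes from −0.08 to 0.16 for siKrt15 against siNeg, from −0.06 to 0.02 for siKrt15 against mock, and from 0.02 to −0.14 for siNeg against mock. Differences below are relative to each array's 75th percentile. Other computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with matplotlib 3.10.9 for plots.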

Results

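Transcript levels were compared in CLDE dental epithelial cells 72 h after mock transfection, non-targeting siRNA (siNeg) or siRNA against Krt15 (siKrt15), with 1 array for each. The series title names the question, whether keratin 15 regulates proliferation in the outer enamel epithelium. Each difference below is between 2 arrays and has no replicate check. The error given is the SD from the scanner's error model. That SD is nearly the same for most bright genes and leaves out differences between cultures.

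Krt15, the type I keratin targeted by the siRNA, was lower in the siKrt15 array than in both controls. Its processed signal was 267 in siKrt15, 1647 in siNeg and 2638 in mock. The log2 difference was −2.88 ± 0.20 (error-model SD) against siNeg, or 7.38-fold lower, and −3.48 ± 0.20 against mock, or 11.2-fold lower. In siNeg Krt15 was lower than in mock by a log2 difference of −0.60. The value rests on 1 probe (NM_008469), at chromosome 11, 99993331 to 99993390 on mm9, whose exon or UTR position was not used here. The direction goes with the titles of the arrays and against their descriptions.

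Other keratins went different ways. The keratins Krt8 (1.43 against siNeg, 1.65 against mock), Krt18 (0.63 and 0.66) and Krt19 (1.32 and 0.96) were higher in the siKrt15 array, as was Krt6b (0.62 and 1.18). These kept their sign in all 8 scalings, although Krt19, a dim gene, was only 0.09 higher against siNeg with normexp. Krt17 was at −0.44 and −0.32, and turned to 0.01 against mock with the signal trend removed. Krt20 and Krt23 were above background in both controls and not in siKrt15, with log2 bounds of −0.57 and −0.72 against siNeg and −1.24 and −1.13 against mock. The abundant basal keratins Krt5 (−0.11 against siNeg) and Krt14 (−0.16) lay near 0, and turned to 0.25 and 0.21 at the highest of the scalings. Over the 16 keratins measured, the median was −0.10 against siNeg (−0.15 to 0.22 over 11 settings) and −0.03 against mock (−0.08 to 0.28), inside the central 95% of random lists, but above it with quantile normalization or the signal trend removed and, against mock, with the stricter filter on dim probes. In each comparison 2 were at least 2-fold higher and 1 at least 2-fold lower.

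**Figure D1:**
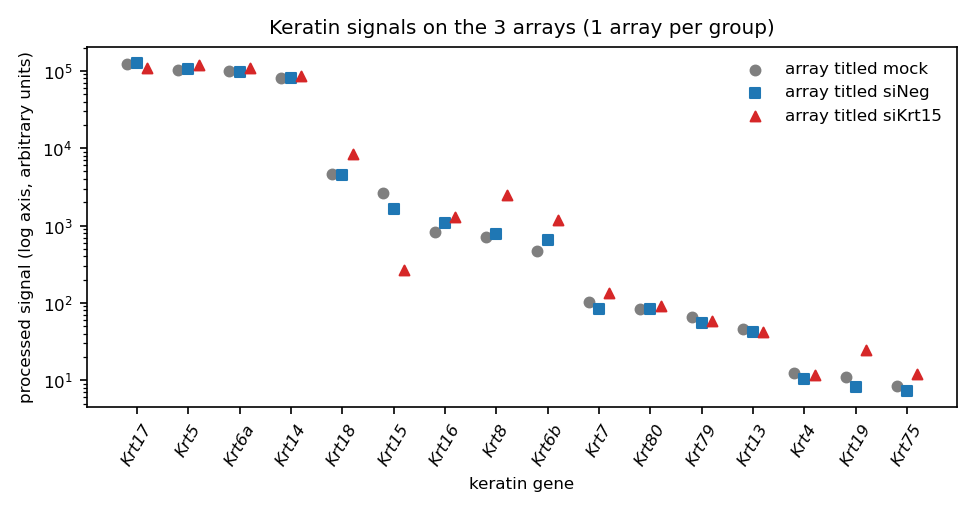
Processed signal (log axis, arbitrary units) of each keratin measured on all 3 arrays, 1 point per array, with mock in grey, siNeg in blue and siKrt15 in red. Krt15 was at 267 in siKrt15 against 1647 in siNeg, while Krt8 and Krt18 were higher in siKrt15 in each of the 8 scalings.

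Against siNeg, the gene lists with the highest medians in the siKrt15 array were those of cell division. Of 28 measured G2/M and mitosis genes, 25 were at least 2-fold higher and 0 at least 2-fold lower, with a list median of 1.52 (2.86-fold), above all 10000 random lists. The kinase Ttk of the spindle checkpoint was higher by 2.35, the spindle motor Kif11 by 2.19, cyclin A2 (Ccna2) by 2.08 and survivin (Birc5) by 2.04. Ttk and Kif11 rest on 1 probe each and were dim in siNeg, with processed signals of 10.1 and 6.4. The error-model SD of Kif11 was 0.31. Of 29 DNA replication and G1/S genes, 9 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.77. Mcm5 of the replicative helicase was higher by 1.96, the origin licensing factor Cdc6 by 1.25 (its probes 0.70 and 1.81), the ribonucleotide reductase subunit Rrm2 by 1.24 and the chromatin assembly subunit Chaf1a by 1.20.

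Genes of cell cycle arrest did not move with them as a group. The 22 CDK inhibitors and p53 targets had a median of 0.02, inside the random range, with 1 of them at least 2-fold higher. That gene was Cdkn2a at 1.11. Ccng1 was at −0.47, Cdkn2b at −0.46 and Cdkn2c at 0.43. The 19 apoptosis regulators had a median of 0.18, above the random range, with 0 at least 2-fold either way, and Cflar, an inhibitor of caspase 8, was at 0.46 and the death receptor Tnfrsf10b at −0.32.

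Lists of TGF-beta targets and interferon genes also had higher medians in siKrt15 than in siNeg. In the list of TGF-beta, YAP and mesenchymal transition genes the median was 0.51 and 4 of 19 were at least 2-fold higher, namely tenascin C (Tnc, 1.91), thrombospondin 1 (Thbs1, 1.77), fibronectin (Fn1, 1.47) and Ccn2 (1.28). The interferon and double-stranded RNA list had a median of 0.45, with 3 of 27 at least 2-fold higher and 1 lower. Ifit1 was higher by 1.97, Rtp4 by 1.78 and Oasl2 by 1.34, while Oasl1 was at −1.48. Both medians lay above all 10000 random lists, but the TGF-beta median was 0.06 with no filter on dim probes and 0.18, inside its range, with the stricter filter. The growth factor and MAPK list stood at 0.22, above its random range but inside it with normexp (0.031) or the stricter filter (0.067), with the ERK phosphatase Dusp6 at 1.14, Fos at 0.83, Egr1 at 0.72 and Hbegf at 0.72. The NF-kB list stood at 0.15, outside its range in 7 of 11 settings (0.026 with normexp, inside), with opposite members: the chemokine Ccl2 at 1.61, Icam1 at 0.75 and Csf3 at 0.73, and lipocalin 2 (Lcn2) at −1.74.

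Lower in siKrt15 than in siNeg was the sterol and lipid synthesis list, with a median of −0.36 (−0.41 to −0.12 over 11 settings), below all random lists, although 0 of 25 were 2-fold lower and 4 were 1.5-fold lower. Insig1 was at −0.67 and the synthase Hmgcs1 at −0.59. The sterol list was also lower in siNeg than in mock, with a median of −0.22, below all random lists. Relative to the median of all genes, it was at −0.29 for siKrt15 against siNeg and −0.25 for siNeg against mock. A response to any siRNA was not tested for this list. The unfolded protein and amino acid stress list had a median of −0.26, inside its random range with quantile normalization or the signal trend removed (−0.040 and −0.038), with Ddit4 at −0.91, Atf3 at −0.80 and the cystine transporter Slc7a11 at −0.73, and 0 of 19 at least 2-fold lower. The mesenchymal cell markers had a median of −0.41, outside the range in 9 of 11 settings, over 10 genes that went both ways, with decorin (Dcn) at −1.07 and Pdgfra at −0.94 against periostin (Postn) at 1.94 and Col1a1 at 0.85. The 14 reference genes also had a lower median, −0.32, which ranged from −0.37 to −0.05 over 11 settings and lay outside the random range in 9 of them. Actb was at −0.50, Eef1a1 at −0.55, Ywhaz at −0.61 and Tbp at −0.43.

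Medians of the epithelial identity lists lay inside the random range against siNeg, namely basal epithelial adhesion (−0.01, 22 genes), keratinocyte differentiation (−0.04, 24), ameloblast and enamel (−0.04, 15), dental epithelial stem and cervical loop (0.06, 19), Notch and stratum intermedium (−0.01, 13) and Wnt, Hedgehog and ectodysplasin targets (0.09, 12). Exceptions were basal adhesion with quantile normalization (0.13) or the signal trend removed (0.15), and Notch with normexp (0.075), which lay above it. Single members stood apart. Of ameloblast genes, the adhesion receptor Adgrf4 was higher by 1.48, with Wdr72 at −0.80, Fam83h at −0.54 and Dspp at −0.52. In this list 11 of 15 genes lay below 0, but only 4 did so in all 8 scalings, and 3 lay above 0 in all. Against mock 8 lay above 0 and 7 below. Higher were the Wnt transcription factors Lef1 by 1.26 and Tcf7 by 1.08, transglutaminase 1 (Tgm1) by 1.16, and the FGF-responsive factors Etv4 by 0.93 and Etv5 by 0.74. S100a9 was at −1.35, Sprr2d at −1.08, and Sprr1a at −0.81. Of basal adhesion genes, Dst was at −0.58, Epcam at 0.53 and Itga6 at 0.41, and of Notch genes Hey1 was at 0.74, Hes1 at 0.56 and Notch1 at −0.43. The Wnt and Hedgehog list members Rnf43 and Bmp4 were at −0.44 and −0.35.

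Medians inside the random range were also found for hypoxia and glycolysis (−0.16; Hk2 −0.65), ribosome biogenesis and MYC targets (0.02; Cad −0.50, Nop56 0.40) and the RNA interference machinery (−0.11; Ago4 −1.17). Endothelial, blood and immune markers, of which 7 of 14 were measured, had a median of −0.28, inside a random range of −0.36 to 0.22 but below the range in 3 of 11 settings. Against mock 8 of 8 measured lay below 0, with a median of −0.37, inside the range but below it in 5 of 11 settings. Cd3e stood at −0.46.

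**Figure D2:**
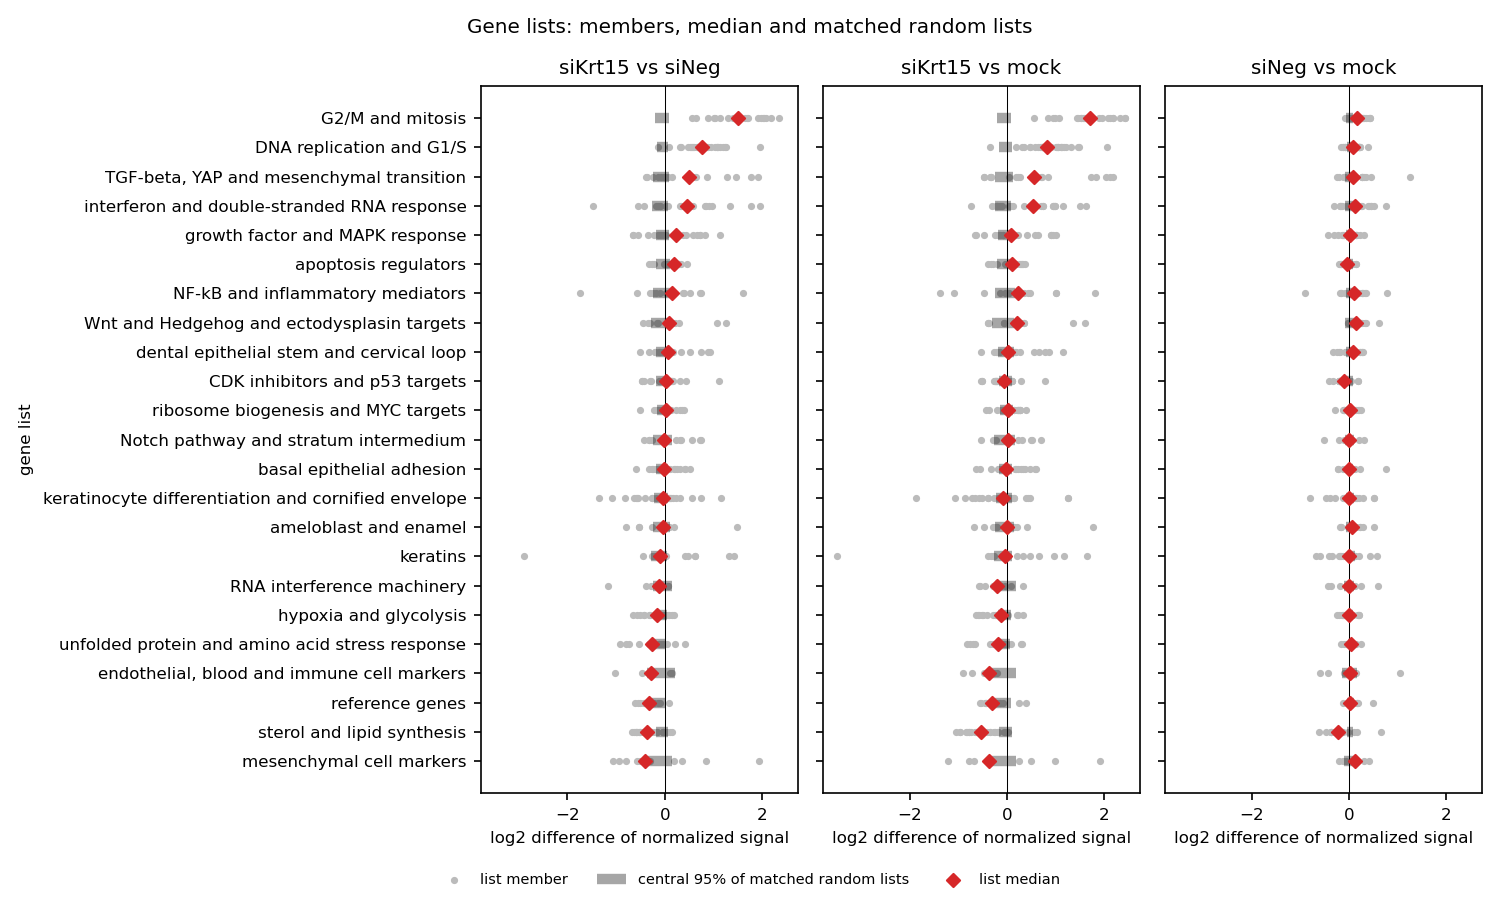
Log2 difference of normalized signal for members of the 23 gene lists (grey points), their median (red) and the central 95% of random lists matched on signal (dark bar), for siKrt15 against siNeg, siKrt15 against mock and siNeg against mock. The G2/M and mitosis median was 1.52, 1.70 and 0.16 in that order, above all random lists in each.

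Over all 17121 genes measured in both arrays, 291 were at least 2-fold higher and 342 at least 2-fold lower in siKrt15 than in siNeg. Higher genes made up 46.0% of these, against 78.1% with normexp, 72.6% with quantile normalization, 79.9% with spike-in scaling and 74.8% with the signal trend removed, but 39.4% with the 75th percentile over spots, 35.7% at 1.5-fold and 18.7% with no filter on dim probes. Most of the higher and most of the lower genes were dim: among the 8561 genes at or above the median signal, 74 were higher and 35 lower. With normexp the G2/M median was 0.84 and the interferon median 0.13.

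Against mock, the G2/M, replication, TGF-beta, interferon and sterol lists again lay outside their random ranges, in a comparison that shares the siKrt15 array. Of 28 G2/M and mitosis genes 24 were at least 2-fold higher and 0 lower, with a median of 1.70, and of 29 replication genes 13 were higher and 0 lower, with a median of 0.83. Ccna2 was higher by 2.42, Kif11 by 2.44 (dim, with a signal of 5.7 in mock) and Mcm5 by 2.05. The TGF-beta, YAP and mesenchymal transition median was 0.56 (5 of 19 at least 2-fold higher, Tnc at 2.17), and the interferon median 0.54 (3 of 26, Rtp4 at 1.63), with 0.23 and 0.19 under normexp. These 4 medians lay above all 10000 random lists. The sterol list was lower, with a median of −0.53, below all random lists, with Hmgcs1 at −0.96 and Insig1 at −0.84.

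In this comparison 9 of 23 list medians lay outside the random range, against 11 for siNeg, and 5 in each comparison lay outside in all 11 settings. The Wnt, Hedgehog and ectodysplasin list was outside here in 8 of 11 settings, at 0.20 (Lef1 1.60, Tcf7 1.35), and the NF-kB (0.23, 10 of 11), mesenchymal marker (−0.36, 6 of 11, but 0.071 with the stricter filter on dim probes) and reference gene (−0.31, 7 of 11) lists were outside as against siNeg. The growth factor (0.08), apoptosis (0.11) and unfolded protein (−0.18) lists lay inside. The apoptosis list lay above its range in 2 of 11 settings, at 0.120 with no filter on dim probes and 0.199 with the signal trend removed. Of 17130 genes measured, 374 were at least 2-fold higher and 213 lower. Higher genes made up 63.7%, against 81.0% with normexp, 82.2% with quantile normalization, 74.6% with spike-in scaling and 83.4% with the signal trend removed, but 55.7% with the 75th percentile over spots, 43.1% at 1.5-fold and 29.4% with no filter on dim probes.

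Against both controls at once, 256 of 16912 genes were at least 2-fold higher in siKrt15 and 112 at least 2-fold lower. Of the 256, 33 were in the G2/M or replication lists, where 0.863 would be expected from list size. Among the 10 highest that met the naming rule were the zinc importer Slc39a4 (2.89 against siNeg and 3.33 against mock; chromosome 15, 76442866 to 76442925 on mm9), the protease inhibitor Ctla2a (2.61 and 2.75), the collagen VI chain Col6a1 (2.60 and 2.53) and osteopontin (Spp1, 2.09 and 2.47). The mitotic regulator Pimreg (2.49 and 2.53), the Aurora A partner Aunip (2.26 and 2.72), and the kinetochore genes Nuf2 (2.28 and 2.17) and Kntc1 (2.13 and 2.32) were also among the 10. So were the exonuclease Exo1 (2.15 and 2.32) and the recombination factor Rad51ap1 (2.08 and 2.18), whose error-model SD against siNeg was 0.21 each. Rad51ap1 rests on 2 probes, and a further probe, measured in both controls, was not well above background in siKrt15. The others of the 10 rest on 1 probe each. Several were dim in siNeg, with processed signals of 17.9 (Spp1), 18.5 (Ctla2a), 21.1 (Aunip) and 26.5 (Slc39a4).

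After Krt15, the lowest gene under the naming rule was the membrane serine protease Tmprss4 (−2.50 against siNeg and −2.49 against mock, 2 probes; chromosome 9, 44980979 to 44981038 on mm9). The dynein light chain Dynlrb2 (−1.80 and −2.08), the skin chemokine Ccl27a (−1.79 and −1.90), otogelin (Otog, −1.61 and −2.23), the keratinocyte exonuclease Trex2 (−1.58 and −1.76) and the protein kinase A catalytic subunit Prkaca (−1.49 and −1.59) followed. The trypsins Try5 (−1.67 and −1.91) and Try4 (−1.62 and −2.13) and the histone H2ac6 (−1.66 and −1.95) have near-identical relatives, so the gene behind their signal is uncertain.

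The 2 counts that follow hold genes with a proper symbol that could be given a bound against both controls. Of 138 such genes above background in siKrt15 alone, the brightest were the interferon-induced Ifit3, at least 4.38-fold higher than in siNeg and at least 4.59-fold than in mock, the cohesin acetyltransferase Esco2 (at least 3.64-fold and 3.82-fold) and Tprg (at least 3.47-fold and 3.66-fold). Of 334 such genes above background in both controls and not in siKrt15, the brightest were Cckar (at least 4.97-fold lower than in siNeg and 6.44-fold than in mock), Lgsn (at least 5.02-fold and 2.19-fold) and Vmn2r67 (at least 3.31-fold and 3.28-fold). Even these were dim, with processed signals of 23.6 for Ifit3 in siKrt15 and 18.8 for Cckar in siNeg. The 2 comparisons share the siKrt15 array. Unchanged arrays simulated from the siNeg to mock differences gave on average 1.92 higher and 2.28 lower genes (at most 6 of each in 100 draws), and siNeg against the other arrays gave 24 higher and 1 lower. The draws left out the wider spread of siKrt15 against siNeg (SD 0.42, against 0.23 for the controls) and its lower signal for dim genes. With quantile normalization or the signal trend removed, 57 genes were lower in siKrt15 than in both controls. Independent lists would share 6.39 and 4.07, and part of the excess may come from the shared array.

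**Figure D3:**
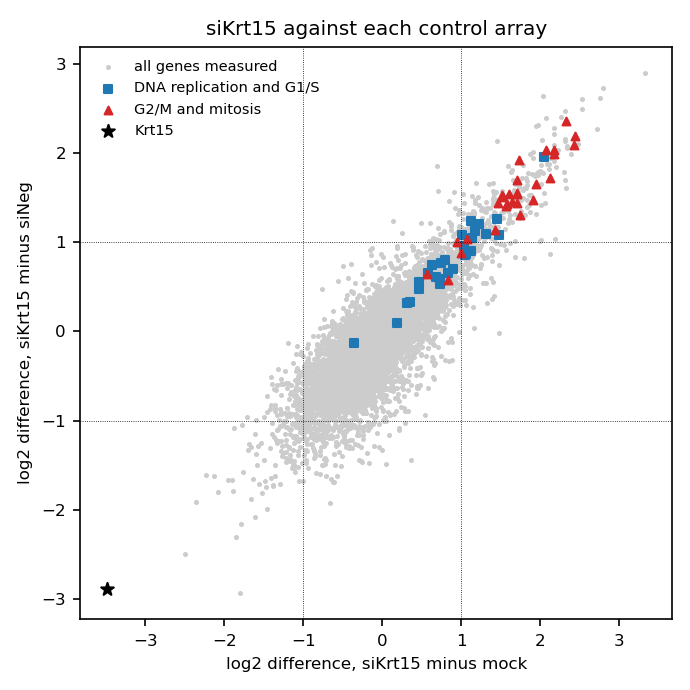
Log2 difference of siKrt15 against siNeg (vertical) and against mock (horizontal) for the 16912 genes measured on all 3 arrays, with replication genes in blue, G2/M and mitosis genes in red and Krt15 as a star. Dotted lines mark 2-fold; 256 genes lie beyond both on the higher side and 112 on the lower side.

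The control arrays differed less. Among genes that met the naming rule, the 5 highest in siNeg against mock were Orm2 (1.03), Orm1 (1.01), C1s2 (1.01), complement C3 (0.99) and the kinetochore gene Ndc80 (0.78). C3 was higher again in siKrt15, by 2.02-fold against siNeg and 4.01-fold against mock. The lowest under this rule, which leaves out the dimmest genes, were Pafah1b2 (−0.88), Cilk1 (−0.88, with probes at −1.61 and −0.15), the cornified envelope gene Sprr2d (−0.80), Gab3 (−0.71) and Pigw (−0.69). Orm1 and Orm2 are near-identical relatives, so their signals cannot be separated with certainty.

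Of 17416 genes, 62 were at least 2-fold higher and 8 lower in siNeg than in mock, and among the 8708 at or above the median signal 2 were higher and 0 lower. The SD over all genes was 0.23, against 0.42 for siKrt15 versus siNeg. The G2/M median was 0.16 with 0 of 28 genes at 2-fold, the interferon median 0.13 (inside its range with the stricter filter, 0.043, or the brightest probe per gene, 0.094) and the sterol median −0.22, among 6 of 23 lists outside the random range, 3 of them in all 11 settings. The replication (0.08, outside in 7 of 11), Wnt (0.14, 8 of 11) and CDK inhibitor (−0.11) lists were the others. Higher genes made up 88.6% of those at 2-fold, against 54.3% with spike-in scaling.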

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

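The counts here were chosen after the data were seen. Probes with no gene in the RefSeq table were not used in the comparisons above. Among 6589 such transcripts measured on all 3 arrays, 15 were at least 2-fold higher and 83 at least 2-fold lower in the siKrt15 array than in both controls. The corresponding counts for siNeg against the other arrays were 12 and 0. Dim genes were lower in siKrt15 in general: in the dimmest of 8 signal bins the median log2 difference from siNeg was −0.34, against −0.08 in the brightest.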

How the results depend on the processing

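The spike-in, signal-trend and spot-percentile scalings were added after seeing the data. Over all alternatives 805 values stayed within their spread or 1.5 times their count, 294 moved and 38 turned direction. The deposited table, the 75th percentile over spots and the median of probes above background moved none of the 18 counts and medians that answer a comparison. Counts are given as higher and lower. With a 1.5-fold threshold they were 821 and 1477 (siKrt15 against siNeg), 998 and 1317 (against mock), 422 and 149 (siNeg against mock) and 683 and 775 (siKrt15 against both controls), and with a 3-fold threshold 83 and 36, 124 and 26, 1 and 0, and 77 and 15. With normexp, whose offset shrinks differences of dim probes, they were 82 and 23, 102 and 24, 0 and 0, and 81 and 17, Krt15 was at −2.64 and −3.23 (siNeg, mock), the G2/M medians were 0.84 and 0.94, and the replication medians 0.58 and 0.64. With no filter on dim probes the counts were 477 and 2070, 646 and 1549, and 836 and 413, with 873 lower than in both controls and a G2/M median of 1.59 against mock. With the stricter filter, which tests fewer genes, they were 136 and 44, 178 and 44, 2 and 1, and 127 and 31. Of the 20 named genes 8 were then left past 2-fold, the medians against siNeg were 1.59 (G2/M) and 0.70 (replication), and the mesenchymal marker median against mock turned to 0.071. For the settings that follow, groups by description apart, the cause was not tested. Quantile normalization left 145 (siNeg), 103 (mock) and 57 (both controls) lower genes and a replication median of 0.83 against siNeg. Removing the signal trend left 136, 104 and 57 lower genes and a G2/M median of 1.60 against siNeg. Spike-in scaling gave 522 and 131 genes against siNeg, 25 and 21 for siNeg against mock, 58 lower than in both controls, Krt15 at −2.64 against siNeg, G2/M medians of 1.76 and 1.78, and replication medians of 1.01 and 0.91. It shifts every gene alike, which put 3 siNeg to mock medians below 0, replication at −0.079, Wnt at −0.021 and interferon at −0.033, while all 3 stayed above their random ranges. The brightest probe per gene gave 13 lower genes for siNeg against mock, G2/M medians of 1.65 and 1.84, and replication medians of 0.69 and 0.73. Taking groups from the descriptions exchanges 2 arrays by construction. Krt15 was then at 2.88 against siNeg, −0.60 against mock and 1.14 against their mean. Counts were 62 and 8 against mock, 374 and 213 for siNeg against mock, and 24 and 1 against both controls, and 0 of the 20 named genes passed. List medians against siNeg turned to −1.52 (G2/M), −0.77 (replication), −0.15 (NF-kB), −0.51 (TGF-beta), −0.18 (apoptosis), −0.22 (growth factor), −0.45 (interferon), 0.41 (mesenchymal markers), 0.32 (reference genes), 0.36 (sterol) and 0.26 (unfolded protein). Against mock the G2/M median was 0.16, replication 0.081, mesenchymal markers 0.12 and reference genes 0.016. Named genes against the mean of both controls turned to −1.23 (Slc39a4), −1.24 (Ctla2a), −1.34 (Col6a1), −1.23 (Pimreg), −0.90 (Aunip), −1.19 (Nuf2), −0.99 (Exo1), −0.97 (Kntc1), −0.86 (Spp1), −0.99 (Rad51ap1), 1.25 (Tmprss4), 0.76 (Dynlrb2), 0.84 (Ccl27a), 0.71 (Try5), 0.69 (H2ac6), 0.56 (Try4), 0.50 (Otog), 0.70 (Trex2) and 0.70 (Prkaca). No paired analysis was possible because each group holds 1 array. The slide as a block was not run, since all 3 arrays share 1 scan. Signal over background limits dim genes, of which 976 were above it in siNeg but not siKrt15 and 362 the other way.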

Other observations

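The kinetochore, recombination, ribosomal protein and clock lists, and the tests of explanations below, were chosen after the differences had been seen, while the G2/M and interferon lists and their comparison with random lists were fixed earlier. Kinetochore genes were higher in the siKrt15 array, with a median of 0.91 against siNeg and 1.16 against mock, and 12 and 18 of 29 at least 2-fold higher (medians of 0.57 and 0.63 with normexp). Ska1 was higher by 2.47 and 2.32, and Ska3 by 2.31 and 1.97. Both were dim, with processed signals of 8.5 and 8.4 in siNeg. Homologous recombination and Fanconi genes had medians of 0.83 and 0.77, or 0.35 and 0.43 with normexp, with 7 and 10 of 21 at least 2-fold higher, among them the helicase Brip1 (1.99 and 2.01) and Hrob (2.04 and 2.22). Brip1 was dim as well, at 7.5 in siNeg. Of the 256 genes higher than in both controls, 19 belonged to these lists and not to the G2/M or replication lists.

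Cytosolic ribosomal protein genes had medians of −0.40 against siNeg and −0.42 against mock, and 79 of 79 lay below 0 in each. Over 11 settings the median ranged from −0.45 to −0.09 and from −0.47 to −0.13, and 59 and 70 of the genes stayed below 0 in all 8 scalings. Random lists matched on signal had medians of −0.15 and −0.11, and both list medians lay below all 10000 of them. For siNeg against mock the median was −0.01, also below all random lists, with 34 genes above 0 and 45 below. Rps3a1 was at −0.92 against siNeg and −0.90 against mock, and Rps6 at −0.63 and −0.59. Clock genes had a median of −0.28 against siNeg and −0.03 against mock, which turned to 0.10 with the signal trend removed. The repressors Nr1d1 (−1.38 and −1.60) and Nr1d2 (−0.96 and −1.09) and the output factor Dbp (−1.02 and −0.85) were lower than in both controls in all 8 scalings.

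The titles and descriptions of 2 arrays name opposite siRNAs. If the descriptions were right, Krt15 would be higher in the array titled siKrt15 than in that titled siNeg, and it was at −2.88. The value argues against exchanged titles, and does not show how the descriptions came about.

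Cell-cycle genes were higher in the siKrt15 array. The first bound set against a scaling or signal trend as the cause was a G2/M median above 1 in each of 8 scalings, and it was not met: normexp gave 0.84. After that value was seen, the bound was replaced by the position among random lists matched on signal, where the median lay above 100% of the lists in every scaling. A scaling that shifts each array by a constant cannot change this position. Only normexp, quantile normalization and removal of the signal trend could have changed it. The G2/M median of siNeg against mock was 0.16 against 1.52 for siKrt15 against siNeg. Relative to other genes its share had an upper 95% bound over resampled members of at most 0.145 in any scaling (plain ratios of medians were replaced by this share after they were seen). On these arrays siNeg thus moved the list far less than siKrt15 did. The bound measures spread among genes and not among cultures, so it cannot exclude a response to any siRNA. That response, the state of the culture, another target of the siRNA and an effect of Krt15 loss cannot be told apart with 1 array per group. An effect of Krt15 loss remains a hypothesis.

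The interferon list had a higher median in the siKrt15 array, with 3 of 27 genes at least 2-fold higher than in siNeg, 1 at least 2-fold lower and 7 below 0. The median lay above 100% of matched random lists in all 8 scalings, although normexp lowered the median from 0.45 to 0.13. Of these scalings, only normexp, quantile normalization and removal of the signal trend could have changed that position. Its place there argues against a signal trend as the whole cause. The siNeg to mock median was 0.13, above its random range in 9 of 11 settings but not with the stricter filter (0.043) or the brightest probe per gene (0.094). Relative to all genes or matched random lists it was 0.194 to 0.316 of the siKrt15 to siNeg median, but the upper 95% bound over resampled members reached 2.07, so a response to any siRNA stays open, although a first bound, a plain ratio under 0.5 in the reported scaling, had been met at 0.281. That response, another target of the siRNA, the culture and an effect of Krt15 loss cannot be told apart with 1 array per group.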
